A study of Danio rerio with 4 samples.

How the data were processed

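The series holds 4 RNA-seq libraries of zebrafish neutrophils, sorted by fluorescence from Tg(mpx:eGFP) larvae at 48 hours post fertilization, 2 from control larvae and 2 from larvae injected with a znf687a morpholino. Per the labels' protocols, RNA was taken from sorted cells, poly(A) RNA was selected with oligo(dT) beads, fragmented and primed with random primers, and libraries were amplified by PCR and sequenced in paired-end mode. Per the submitters' processing notes, the tools used were fastp, HISAT2 2.0.4, Bowtie2 2.2.6 and RSEM 1.2.12, with the GRCz11 genome; their settings and the annotation are not given in the sources used here. No molecular identifiers are mentioned in the labels, so counts of PCR copies are not independent molecules, and floors given in counts cover counting error only.

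Each library has 1 deposited text file with 5 fields of 8 characters per line: gene identifier, transcript identifier, length, expected count and FPKM. The expected count was deposited by the authors as a whole number, not normalized, per the file headers and the values. The FPKM (fragments scaled by length and library total) was deposited by the authors in the last field, per the file headers. Only genes with a count of 1 or more are listed. Identifiers are shortened to their first 8 characters, and all entries of all 4 files share 1 pair of shortened identifiers, so the files do not pair counts with gene names and 0 identifiers could be matched to a table of names. For that reason the log2 fold changes of znf687a and gfi1aa, the 30 gene lists and the marker lists of other cell types, all fixed before the data were examined, were not analysed here.

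Entries were matched between files by length. The 4 files list genes in 1 common order, so an order-keeping alignment of the lengths was computed, in which equal lengths may match and abundant genes weigh more. It gave 20896 genes, 10136 of them in all 4 files; 20288 of the 20896 were the same when the files were joined in the reverse order, and so were all 10136. The match was checked with a quantity the alignment does not use, the ratio of the listed length to the length used for FPKM. Up to a constant per file, it follows from count, length and FPKM. Among 5105 genes with at least 200 counts in all 4 files, 5105 had ratios within 0.01 of each other in all files. Since the ratio partly follows from the length, 2637 of these genes that share their length with another were exchanged with a gene of equal length, and 26.96% then had ratios within 0.01, against all 2637 as joined. In simulated files with known answers, 7 of 17659 genes joined over several files were joined wrongly, and 0 of the 10136 joined in all 4. The ratio check leaves out genes missing from any file, so their match rests on the alignment and on the simulated files. Those simulated files took their genes and listing patterns from the join itself. Genes unlisted in a file were given a count of 0; whether the submitters applied a further filter is not given in the sources used here.

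The 4 totals of expected counts were 18823020, 17079972, 11387372 and 10601573 for control 1, control 2, morpholino 1 and morpholino 2. Count, length and FPKM of a gene give a total, and the smallest over well-covered genes was taken as the total behind the FPKM values. That holds only if the gene giving it used its full listed length, which was not checked. On that assumption the listed genes hold 70.3%, 75.2%, 70.9% and 71.9% of it. The number of genes expected at the smallest total was computed from each gene's count. CPM are counts scaled by the total of listed genes, and normalized CPM are scaled by TMM factors.

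Groups were compared with edgeR 4.0.16 (TMM factors, filterByExpr with its minimum count of 10, glmQLFit and glmQLFTest, two-sided) in R 4.3.3, with group as the only term and a Benjamini-Hochberg adjusted p under 0.05 as the threshold; expected counts were already whole. Standard errors are approximate, the log2 difference divided by the square root of the F statistic. Alternatives were DESeq2 1.42.0, limma-voom and limma-trend (limma 3.58.1, the latter on log2(FPKM + 1) for genes at an FPKM of 1 or more in 2 libraries), other scalings and filters, genes listed in all 4 files, each library left out, and the replicate number as a block. DESeq2 gave 4861 genes no adjusted p, and these stayed out of its calls. Joint losses were compared with the number expected from independent losses within classes of abundance, in bins of 0.5 log2 units of the mean CPM in the libraries that list the gene. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

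The rule for single genes was fixed before the data were examined. It asked for genes past the threshold with a gene symbol or, where none passed in a direction, the 5 with the smallest p among those with a mean CPM of 10 or more and both morpholino libraries on the same side of both controls, together with every measured study gene and up to 4 members of each gene list. None passed, symbols could not be applied, and without names only 2 genes per direction are given. The edgeR step was tested on counts simulated at the estimated spread, with 200 genes changed by known amounts and 15016 genes left after its filter. It called 4% of the 4-fold changes and 29% of the 16-fold changes, with the right sign in 95.5% and 98.9% of those tested. Among unchanged genes it called 3. With a dispersion of 0.01 it called 99% and 100%, and 13 unchanged genes.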

Results

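RNA was profiled in neutrophils of zebrafish larvae at 48 hours post fertilization. The cells were sorted from the reporter line Tg(mpx:eGFP), in which the promoter of mpx, the myeloperoxidase gene of neutrophils, drives green fluorescence. The 4 poly(A) RNA-seq libraries formed 2 groups of 2. The control group came from larvae of the reporter line, and the other from reporter larvae injected with a morpholino against znf687a, an antisense oligonucleotide that lowers the function of its target. The control titles name no injection and no control morpholino. Effects of injection itself therefore cannot be told apart here from those of the znf687a morpholino. The expected counts of control libraries 1 and 2 summed to 18823020 and 17079972, and those of morpholino libraries 1 and 2 to 11387372 and 10601573. The labels do not say that the libraries of a group came from separate clutches, so p-values measure only the spread between these samples, which may be technical.

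The comparison asked how the neutrophil transcriptome differed after the znf687a morpholino. Fewer genes were listed with a count of 1 or more in the morpholino libraries. Control libraries 1 and 2 listed 19887 and 17109 genes, and morpholino libraries 1 and 2 listed 13640 and 12229. The group means were 18498 ± 1964.3 genes in controls and 12934.5 ± 997.7 in morpholino libraries (SD, n = 2). When all libraries were scaled down to the smallest total count, the means were 18440.5 ± 1921.2 and 12933 ± 995.6 genes (SD, n = 2). Each morpholino library lay below each control before and after this scaling, and the gap was larger than the spread within either group. With 2 libraries against 2, the smallest two-sided p of an exact permutation test is 0.333, so that test could not pass a threshold of 0.05 here, and no other test of these means was run. The 100 most abundant genes took 33.4% and 33.7% of the counts in the controls and 38.5% and 40.2% in the morpholino libraries.

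**Figure D1:**
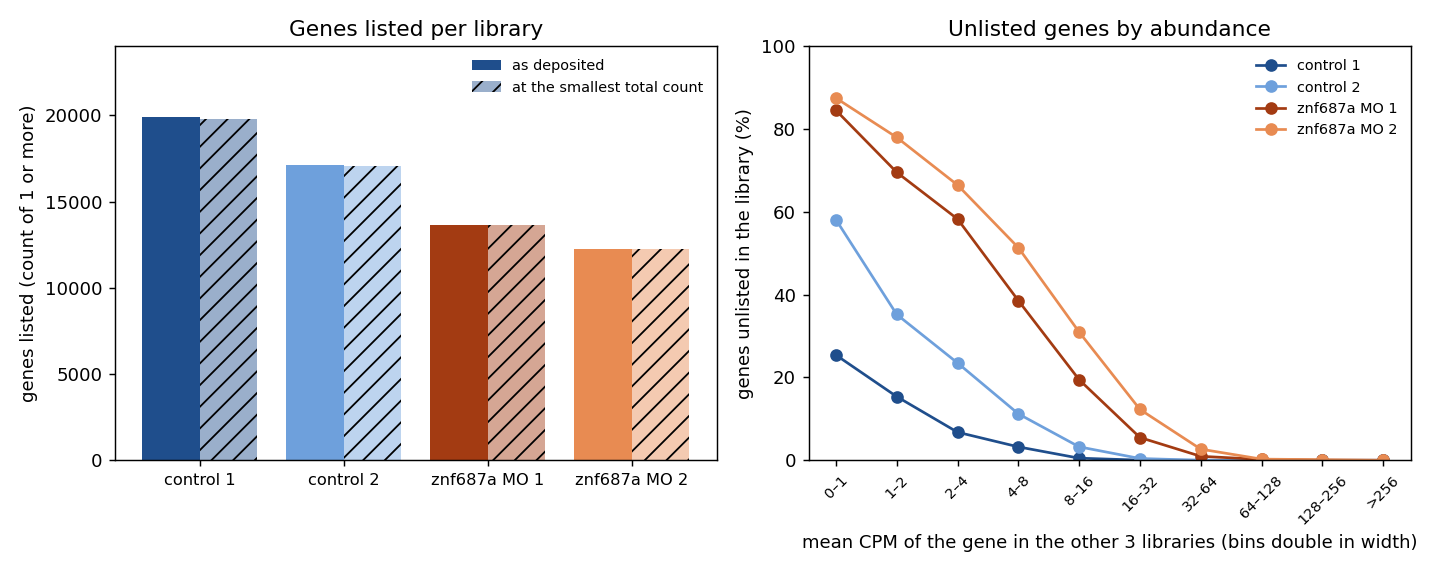
Left, genes with a count of 1 or more in each library, as deposited (solid bars) and expected at the smallest total count (hatched bars); right, percentage of genes unlisted in each library (vertical axis) in bins of their mean CPM (counts scaled by the library total) in the other 3 libraries (horizontal axis). At 8 to 16 CPM, 0.51% and 3.25% of genes were unlisted in the controls and 19.5% and 31.0% in the morpholino libraries. The other 3 libraries include both controls for a morpholino library but only 1 control for a control library, so the bins are not alike between groups.

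Across the libraries, 20896 genes were listed at least 1 time, and 10136 of them in all 4 libraries. Genes listed in both controls and in neither morpholino library numbered 2426, against 18 genes listed in both morpholino libraries and in neither control. A further 3816 genes were listed in both controls and 1 morpholino library, and 222 in both morpholino libraries and 1 control. The genes missing from the morpholino libraries were mostly of low or moderate abundance. Among genes at 8 to 16 CPM on average in the other 3 libraries, 561 of 2883 were unlisted in morpholino library 1 and 887 of 2864 in morpholino library 2. In the controls the same CPM range had 14 of 2763 genes unlisted in library 1 and 88 of 2710 in library 2. The other 3 libraries include both controls for a morpholino library but only 1 control for a control library, so the classes are not alike between groups. At 32 to 64 CPM, no gene was unlisted in either control, and 0.96% and 2.69% were unlisted in morpholino libraries 1 and 2. The count of genes listed only in controls was 4836 without control 2, 4938 without morpholino library 1 and 3730 without morpholino library 2, since fewer libraries then had to list or lack a gene. Leaving out control 1 gave 2993. The 18 genes listed only in morpholino libraries became 226 without control 1, 32 without control 2, 151 without morpholino library 1 and 145 without morpholino library 2.

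At 32 CPM or more in both controls, 3 genes were listed in neither morpholino library, and no gene met this condition for any other pair of libraries, the reverse comparison included. At 64 CPM or more no gene met it for any pair, the morpholino pair included. The files do not pair their entries with gene names, so genes are described here by their listed length in bases; each length given for a gene chosen by test was shared by 4 genes and does not identify it. Genes unlisted in a file were taken as 0 counts; whether the submitters also left out genes by another quantity is not given in the sources used here, and the bounds that follow hold only if they did not. A gene of 597 bases had 1362 and 984 counts in the controls, or 64.96 ± 12.48 normalized CPM (SD, n = 2), and was unlisted in both morpholino libraries. Its CPM there was at least 238-fold lower, against a floor of 3 counts per library that covers counting error only. At 32 to 64 CPM in the other libraries, 0.96% and 2.69% of genes were unlisted in morpholino libraries 1 and 2. Sampling of reads predicts a share near 0 there. The floor does not cover such losses, so it sets no bound on the level in the cells. A gene of 5392 bases had 678 and 699 counts in the controls, or 38.31 ± 2.227 normalized CPM (SD, n = 2), and was unlisted in both morpholino libraries. Its CPM there was at least 141-fold lower against the same floor, which again sets no bound on the level in the cells. Averaged over the other libraries, this gene lay in the lower class of 16 to 32 CPM. In that class 5.5% and 12.28% of genes were unlisted in morpholino libraries 1 and 2. The remaining gene, of 1777 bases and picked after its values were seen, had 730 and 4865 counts in the controls, a mean of 161.8 ± 174 CPM (SD, n = 2), so the spread between the controls exceeded their mean.

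Among genes with a mean CPM of 10 or more that were higher in both morpholino libraries than in both controls, a gene of 168 bases had the smallest p. Its counts were 280 and 346 in the controls and 886 and 1167 in the morpholino libraries, which gave 17.45 ± 3.232 and 94.25 ± 19.2 normalized CPM (SD, n = 2 per group). The log2 difference was 2.43 (approximate SE 0.37, edgeR unadjusted p = 0.00178, adjusted p = 0.24). A gene of 3347 bases had 127 ± 7.242 normalized CPM in controls and 388.5 ± 32.32 in morpholino libraries (SD, n = 2 per group). Its log2 difference was 1.61 (approximate SE 0.26, edgeR unadjusted p = 0.00218, adjusted p = 0.24). The genes of 597 and 5392 bases had unadjusted p-values of 0.00035 and 0.00133 by edgeR, and the same adjusted p of 0.24. Both were unlisted in both morpholino libraries. All 1894 tested genes of that kind had an unadjusted p under 0.05 by edgeR, so such a p does not by itself mark a change. None of these 4 genes passed the threshold by edgeR on all libraries. DESeq2 called all 4, with adjusted p-values of 0.00104 and 3.66e-05 for the genes of 168 and 3347 bases and 4.1e-09 and 5.06e-07 for those of 597 and 5392 bases. limma-voom called the genes of 597 and 5392 bases (adjusted p = 0.0174 for both), and so did edgeR without morpholino library 1 (adjusted p = 0.0487 for both). Over all settings the adjusted p ranged up to 1 for each gene. That their values separated the groups in 4 of 4 libraries was a condition of their choice.

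edgeR's quasi-likelihood test called 0 of 16797 genes at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.24. At an unadjusted p under 0.05 there were 2181 genes, against 840 by chance, a figure that assumes evenly spread p-values. The other splits of the libraries into pairs gave 603 and 121 genes by the same test. With the filter set to a mean CPM of 10 or more there were 284, against 478 by chance. Of the 2181, 2079 were lower and 102 higher in the morpholino group. The lower set contained all 1894 tested genes that were unlisted in both morpholino libraries, 176 genes listed in all 4 libraries and 9 others. Those 1894 genes passed the filter through the controls alone, and all of them fell under 0.05. Their number is therefore no evidence of a change. The higher set contained all 13 tested genes unlisted in both controls, 87 genes listed in all 4 libraries and 2 others. Tested alone, the 10136 genes listed in all 4 libraries gave 0 calls by edgeR and 469 genes at an unadjusted p under 0.05, of which 242 were lower and 227 higher, against 507 by chance; this restriction also removes any gene that fell to 0 in a library. Other tools called more: DESeq2 called 425 genes, 398 of them lower in the morpholino group, and limma-voom called 767, 759 of them lower. DESeq2's lower calls included 381 genes unlisted in both morpholino libraries; restricted to genes listed in all 4 libraries, DESeq2 called 26, with 11 higher and 15 lower. edgeR called 520 genes without morpholino library 1 and 0 without any other library. The genes at an unadjusted p under 0.05 were 117 lower and 61 higher without control 1 (893 by chance), 100 and 49 without control 2 (921 by chance), 3891 and 561 without morpholino library 1 (966 by chance), and 2621 and 305 without morpholino library 2 (965 by chance). The excess over chance was thus absent when either control was left out and present when either morpholino library was. Each of these fits took its spread from the group that kept both libraries, and the morpholino pair differed more than the control pair. The counts therefore do not tell how far the excess rests on any single library.

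Among the genes listed in all 4 libraries, libraries of 1 group differed about as much as libraries of different groups. The log2 difference between libraries had an SD over genes of 0.93 for the control pair and 1.27 for the morpholino pair, against 0.97 to 1.2 for the 4 pairs across groups. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.88 between the controls and 0.79 between the morpholino libraries, and 0.79 to 0.88 across groups. Among 4714 such genes with a mean of 32 CPM or more, 21 differed over 8-fold between the controls and 46 between the morpholino libraries, against 8 to 50 across groups. The biological coefficient of variation estimated by edgeR was 107% over all tested genes and 48.3% over the genes listed in all 4 libraries. Levels of znf687a, of gfi1aa and of the neutrophil and other cell type markers were not analysed here, since the deposited entries carry no gene names.

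**Figure D2:**
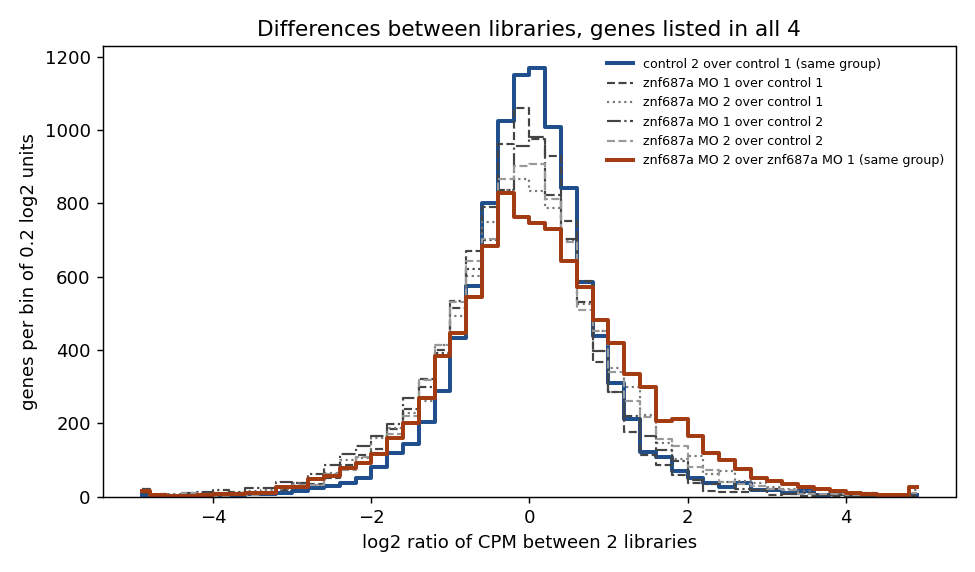
Distribution of the log2 ratio of CPM between 2 libraries (horizontal axis) over the 10136 genes listed in all 4 libraries, as the number of genes per bin of 0.2 log2 units (vertical axis); each line is 1 pair of libraries, with thick lines for pairs of 1 group and thin lines for pairs across groups. The outermost bins hold all larger ratios, and the morpholino pair is the widest, with an SD of 1.27.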

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

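Settings for the counts at an unadjusted p under 0.05, DESeq2 on genes listed in all files, and listing at 10 counts or equal totals were chosen after the data had been seen. edgeR called 0 genes under every other scaling and filter, with the replicate block and on genes listed in all files, and so did limma-trend, while DESeq2 called 425, limma-voom 767 and DESeq2 on genes listed in all files 26. Leaving out 1 library gave 0 to 520 calls (520 without morpholino library 1), with the lone library of a group assumed to vary like the others. The 2079 lower genes at an unadjusted p under 0.05 became 1192 with no filter, 173 at a mean CPM of 10 or more, 242 on genes listed in all files (332 by DESeq2), 1224 by limma-trend and 100 to 3891 with 1 library left out. The 102 higher genes became 215 by DESeq2, 227 on genes listed in all files (323 by DESeq2), 166 by limma-trend and 49 to 561 with 1 library left out. Genes listed in all files leave out those lost from the morpholino libraries by construction; elsewhere the cause was not tested. Median log2 differences were -0.26 with TMM, -0.19 with RLE, -0.15 with upper-quartile factors and -0.28 with totals only.

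Genes listed only in both controls numbered 2426, with 2141 at 10 counts or more, 2409 at equal totals and 2993 to 4938 with 1 library left out; the reverse pattern held 18, 25, 18 and 32 to 226 genes. Deviations of same-numbered libraries from their group means correlated at 0.16 across 16797 genes. With 2 libraries per group, both pairs of same-numbered libraries give this same value. The labels do not say what the numbers mark. With the replicate block, 328 genes were lower and 116 higher at an unadjusted p under 0.05 by edgeR, against 840 by chance. Fitted log2 differences were 2.25 to 2.63 for the gene of 168 bases and 1.53 to 1.76 for that of 3347; their direction was a condition of their choice, so its stability was not tested. Those of 597 and 5392 bases, at 0 in both morpholino libraries, have fitted values set by the prior count or pseudocount, which are not given. Past the threshold, by DESeq2 in each case, were the genes of 168 and 3347 bases in 2 settings each; those of 597 and 5392 bases passed in 3 each, by DESeq2, limma-voom and edgeR without morpholino library 1. Leaving out other cell types' markers, the gene list tests and all settings for znf687a and gfi1aa were not run for want of gene names, nor was the pseudocount of 0.1, as FPKM was not the main unit.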

Other observations

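The tests of read depth, of fewer RNA molecules and of joint losses by odds ratio were chosen only after the results they bear on had been seen.

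The morpholino libraries listed fewer genes than the controls. Read depth as the whole cause is argued against, since at the smallest total count the lower control still listed 3445 genes more than the higher morpholino library. Fewer RNA molecules sampled per morpholino library may account for the gap. At 8 to 16 CPM in the other libraries, the lower morpholino share of unlisted genes was 5.99 times the higher control share. Sampling of reads predicts a share near 0 there. The other libraries include both controls only for a morpholino library, which can raise this ratio. The ratio also restates the gap within a class of abundance, and the causes named at the end of this paragraph would raise it too. It therefore does not tell fewer RNA molecules from those causes. At 4 to 8 CPM, 3.24% and 11.2% of genes were unlisted in the controls, below the morpholino shares of 19.5% and 31.0% at 8 to 16 CPM. Genes at 1 to 3 counts were also rare, at 1.82% and 0.82% of listed genes in the controls and 0.77% and 0.52% in the morpholino libraries. A filter applied by the submitters, or an effect of the morpholino or its injection on the number of expressed genes, or on the RNA content or number of sorted cells, stays open and was not tested.

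Genes listed in both controls and in neither morpholino library could be those lost by chance, independently in each morpholino library. A ratio of joint losses to independent losses at the same abundance had been planned as the test, but it decides nothing: the 2426 genes were 1.12 times the 2157.2 expected, and the losses of each library capped that ratio at 1.73, below the 2.33 it was to be set against. The odds ratio of joint losses has no such cap; it was 1.89 for the morpholino pair, against 2.64 to 12.27 for pairs that cross the groups and 15.53, on 18 genes, for the control pair. All these values lay above 1, also for pairs that share no treatment. Abundance can still differ between genes within a class, which raises the odds ratio of independent losses. The odds ratio therefore does not decide whether the losses were independent, and it does not rank pairs with unlike numbers of losses. Some of these genes, such as those of 597 and 5392 bases, may also have been lower after the morpholino, which stays open.

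Most genes at an unadjusted p under 0.05 by edgeR were lower in the morpholino group, 95.3% of them. The imbalance lay mostly in genes unlisted in both morpholino libraries, which were 1894 of the 2079 lower genes. Without genes unlisted in both libraries of a group, 185 lower and 89 higher genes were left, of 14890 tested. Those are fewer than evenly spread p-values would give at that threshold. Among genes with a mean of 10 CPM or more the share lower was 60.9%, of 284 genes against 478 by chance. Why the 1894 genes were unlisted stays open. The 4 libraries form 3 splits into pairs, too few for a share under 0.05: the real split, 1 of 3, gave 2181 genes at an unadjusted p under 0.05 by edgeR against 603 for the highest other. By DESeq2 it gave 425 calls against 149, again 1 of 3.

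Differences between libraries ran weakly with gene length across groups. Over the 10136 genes listed in all 4 libraries, Spearman's rho across genes between length and the log2 difference was -0.13 to -0.07 for the 4 pairs across groups, morpholino over control, and -0.01 and 0.02 within the control and morpholino groups. Of the 21 genes over 8-fold apart between the controls, 19 were higher in control 2.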
